A study of Homo sapiens with 7 samples.

How the data were processed

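The samples were organoids grown from WTC-11, an established line of human induced pluripotent stem cells, in versions that carry a fluorescent tag on a tubulin or a tight junction gene. RNA of single cells was captured with the 10x Genomics droplet method, which tags each molecule with a unique molecular identifier (UMI). Per the labels' protocols, organoids were pooled before capture, 24 of each kind at day 6, 10 at day 28 and 2 at day 104, the last number being given for skin organoids. The 10 tables of the 7 samples were all used. Of the 4 day 6 conditions, the tables of SEO with and without LDN were told apart by reading the letters WL and NO-LF in their names as with and without LDN, and values for this pair rest on that reading. The name of the day 28 SE library holds LF, so SE may have received LDN and FGF, which the labels leave open and every comparison with SE depends on. The series text calls the day 104 skin sample cSKO where its own label says cvSKO, and the label was followed.

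The deposited values are whole-number UMI counts per gene and cell, for 36601 genes in the same order in every table, and the authors made them with Cell Ranger 6.1.2 on the GRCh38 genome, per the submitters' processing notes. The gene annotation, the treatment of intronic reads and the limits used to filter cells are not given in the sources used here. Checked on the tables, no cell held more than 10% mitochondrial UMIs or fewer than 1000 UMIs, so cells had been filtered before deposit. A gene is identified by its symbol in the tables, and coordinates and gene lengths were taken from the GENCODE annotation of GRCh38, which may differ from the one used for counting. Total deposited UMIs ran from 9101208 in day 6 LPM to 128440116 in day 28 Amnioid, and median UMIs per cell from 3915 in day 104 cvSKO to 14879 in day 104 Amnioid.

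Cells were kept at 500 or more detected genes and under 20% mitochondrial UMIs, which removed 2 cells of day 104 Amnioid and 4 of day 104 cvSKO. How doublets were treated before deposit is not given in the sources used here. They were called by simulating 1 pair of summed cells for each cell of a library and scoring every cell by the share of simulated pairs among its nearest neighbours. The highest scores were called up to a rate of 0.8% for every 1000 cells, and calls removed 2.66% of day 6 LPM to 13.6% of day 104 cvSKO cells. Each library was clustered alone, the day 6 pool as one, on 2000 variable genes chosen by Pearson residuals, with 30 principal components, 15 neighbours and the Leiden method at resolution 1. Of 130 clusters 25 stayed unnamed. A marker counted for a cluster when it lay at least 2-fold over the mean of all clusters and was seen in at least 10% of cells. A class needed at least 3 such markers, more than 50% of its list and a mean log2 ratio of at least 1, or, for mesenchyme, 6 of the 43 markers of its lists together. A cluster stayed unnamed when its 10 leading genes held more markers of another class than of its own. Clusters of low depth with no marker of their own in the lead also stayed unnamed. For the first rule 1 gene could be enough. The unnamed day 104 cvSKO cluster of 1798 cells had 12 of 12 fibroblast markers and only FABP4, an adipocyte marker, against it. Such clusters need not be another cell type, and their cells are missing from the share of the class they came closest to. The doublet rate, these thresholds and the merging of lists into classes were set after the cluster profiles had been seen, so a class is a description of these tables. Classes of different libraries come from different clusters, and the mesenchyme-like class in particular holds clusters closest to lateral plate, smooth muscle or fibroblast lists, or named only by the mesenchyme lists together, at day 28 and clusters closest mostly to the fibroblast list at day 104 and day 128.

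For each condition raw counts were summed over cells and scaled to a total of 1000000 per condition (CPM). Ratios are log2 of CPM + 1 in the first over the second condition, which understates the ratio of genes with few counts. A list's value is the median over members at 5 CPM or more in either condition. It is given with a counting interval from 1000 Poisson draws, with the number of members at least 2-fold higher or lower on that scale, and with its percentile among 10000 random lists matched on mean expression in 20 bins, which only describes these tables. With 1 sample per condition cells are not replicates, so no test was run on cells. Sums carry exact 95% Poisson intervals and shares exact 95% Clopper-Pearson intervals, for counting error only. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs.

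The comparisons, 38 gene lists, cell type markers, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, per comparison, genes among the 10 largest and 10 smallest log2 ratios with a pseudocount of 10 CPM among genes at 50 CPM or more in the higher condition. Mitochondrial, ribosomal protein and sex-linked marker genes and genes with only a clone name were left out. Within each list up to 4 measured members with the largest absolute ratio are named, and ID1 and ID3 at day 6 and ISL1, GABRP, VTCN1, TP63, KRT5, HAND1 and SOX10 are always named. Some genes that the rule takes are not reported here. Lists that hold naming markers of a class are also lists of the comparisons, so such a list is not independent of the class names. In all, 11 comparisons were made over all cells and 6 within a class.

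The alternatives were a pseudocount of 10 CPM, median-of-ratios size factors, equal weights for cells, at least 1000 genes with under 10% mitochondrial UMIs per cell, doublet calls kept, all list members counted, Leiden resolution 2, and all cells in place of fibroblast-like cells. The list computation was tested on simulated data drawn from the means of day 28 SE and Amnioid over 29583 genes, 200 of them changed. In lists of 12 genes it returned medians of 0.48, 0.95, 1.94 and -0.95 for true log2 ratios of 0.5, 1, 2 and -1, and 0.01 for an unchanged list, which still had percentile 96.1. A high or low percentile alone is therefore not read as a change. All other simulated genes differed by counting error only, unlike genes of the real conditions. The simulation thus does not measure how percentiles behave in the real comparisons. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.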

Results

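Single-cell RNA sequencing was available for 10 conditions of organoids grown from WTC-11, an established line of human induced pluripotent stem cells, with 1 sample of each. The labels name SEO, SEO with LDN added on day 3, cSKO and LPM at day 6, SE, Amnioid and cSKO at day 28, Amnioid and cvSKO at day 104, and vSKO at day 128. Per the series text, cSKO are cranial and vSKO ventral skin organoids and LPM is lateral plate mesoderm. LDN is the usual short name of a small-molecule inhibitor of BMP receptors. The 4 conditions of day 6 were pooled in 1 library and told apart by oligonucleotide tags, while every other condition had a library of its own, so there library and condition cannot be told apart.

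After filtering and removal of doublet calls, day 6 gave 1992 cells of SEO, 982 of SEO with LDN, 1433 of cSKO and 989 of LPM, with medians of 10849.5, 11377.5, 10952 and 8722 unique molecular identifiers (UMIs) per cell. Day 28 gave 8069 cells of SE, 7711 of Amnioid and 11299 of cSKO, at medians of 10965, 13807 and 6872 UMIs. Day 104 gave 4082 cells of Amnioid at 14513.5 UMIs and 14730 of cvSKO at 3468.5 UMIs, and day 128 vSKO gave 3526 cells at 11277 UMIs. Summed UMIs per condition ran from 8768896 in day 6 LPM to 115704025 in day 28 Amnioid. With 1 sample per condition no test of a difference was possible and no difference has a replicate check. Intervals are exact 95% Poisson intervals for sums and exact Clopper-Pearson intervals for shares, and both cover counting error only.

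Among the named classes of day 6 SEO the largest was amnion-like, at 46.9% (44.7 to 49.2%) of cells, followed by glia or neural crest-like cells at 9.59% (8.33 to 11%), neuron-like cells at 3.31% (2.57 to 4.20%) and neural progenitor-like cells at 1.56% (1.06 to 2.20%). With LDN the amnion-like share was 40.5% (37.4 to 43.7%) and the neuron-like share 5.40% (4.07 to 7.0%). In cSKO 5.44% (4.33 to 6.75%) of cells were amnion-like and 81.4% stayed unnamed, most of them in clusters led by RAMP1, MAF and LPL or by cell cycle genes. Unnamed cells made up 38.6% of SEO, 42.8% of SEO with LDN and 0.303% of LPM. Unnamed clusters whose markers came closest to the amnion list held 33.3% of SEO, 41.2% of SEO with LDN and 24.2% of cSKO cells. LPM held 88.9% (86.8 to 90.8%) mesenchyme-like and 10.2% (8.40 to 12.3%) endothelial-like cells. These shares are values and not a comparison of cluster sizes, since the genes that name a class also differed between conditions, and the amnion-like share of cSKO was 9.35% at a finer clustering, 9.76% with doublet calls kept and 11.3% with a stricter cell filter. The amnion-like shares of SEO and SEO with LDN also left their intervals, falling at the finer clustering and rising under the other settings.

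**Figure D1:**
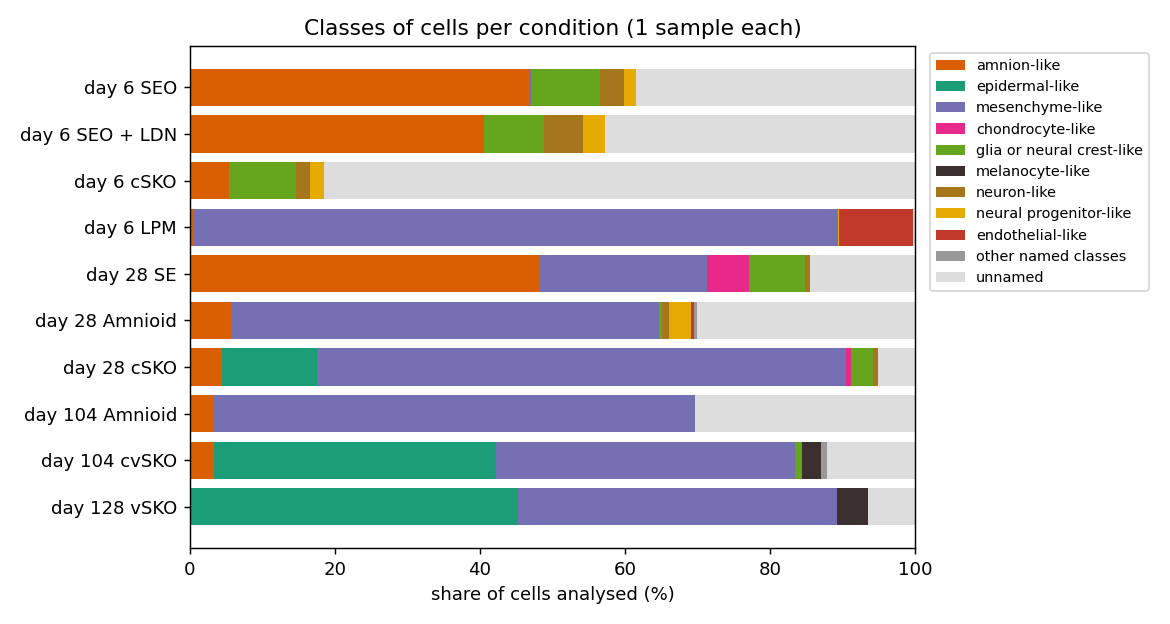
Share of the cells analysed in each class (horizontal axis, percent) for the 10 conditions (vertical axis), with 1 sample per condition. Amnion-like cells held 46.9% of day 6 SEO and 48.1% of day 28 SE, mesenchyme-like cells 88.9% of day 6 LPM, and epidermal-like cells 38.8% of day 104 cvSKO and 45.2% of day 128 vSKO.

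The first comparison asked what the BMP receptor inhibitor did to SEO cells by day 6. Transcripts of BMP targets lay lower with LDN. Of 10 measured targets 3 were at least 2-fold lower and none 2-fold higher (median log2 ratio -0.67, counting interval -0.82 to -0.65, percentile 0 among 10000 random lists matched on expression). MSX1, a homeobox gene induced by BMP, stood at 10.5 CPM (8.76 to 12.4) against 50.4 CPM (47.6 to 53.3), BAMBI, a decoy receptor of the pathway, at 15.4 against 48.4 and SMAD9, one of its signal transducers, at 5.82 against 17.3 CPM. ID1 and ID3, inhibitors of basic helix-loop-helix factors, were at 258 CPM (249 to 267) against 413 CPM (405 to 421) and 129 CPM (123 to 136) against 255 CPM (249 to 262). All 11 measured amnion markers stayed within 2-fold (median log2 ratio -0.31, counting interval -0.35 to -0.22, percentile 0.01), among them IGFBP3 at 434 against 666, WNT6 at 76.5 against 49.5 and GATA2 at 15.8 against 21.7 CPM. Neuron markers lay higher with LDN, 5 of 8 by at least 2-fold (median log2 ratio 1.03, counting interval 0.89 to 1.14, percentile 100), with TUBB3, a neuronal tubulin, at 85.4 against 41 and the neurofilament genes NEFM and NEFL at 37.4 against 9.93 and 14.6 against 3.49 CPM.

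Among single genes the chemokine gene CXCL14 was at 388 CPM (378 to 399) against 72.5 CPM (69.1 to 75.9) with and without LDN, and CRABP1, which encodes a retinoic acid-binding protein, at 431 against 143 CPM. MIR205HG, the host gene of an epithelial microRNA, was at 62.5 against 23.3, and the homeobox genes IRX3 and IRX2 at 73.8 against 37.6 and 60.7 against 32 CPM. Lower with LDN were CGA, the common subunit of the glycoprotein hormones, at 6.84 CPM (5.48 to 8.44) against 84.1 CPM (80.5 to 87.8), the trophoblast aromatase gene CYP19A1 at 1.42 against 9.11, ANKRD1 at 7.24 against 60.4, the lipase gene LPL at 14 against 73.5 and the keratin gene KRT7 at 37.4 against 93.1 CPM. Of 5 smooth muscle and pericyte markers 2 were at least 2-fold lower, TAGLN at 66.4 against 168 and CNN1 at 5.11 against 11.5 CPM. Cell cycle genes stayed within 2-fold, with a median log2 ratio of -0.42, and the cranial mesenchyme list had a median of 0.64 with OTX2 at 12.7 against 6.89 CPM. Both conditions came from the same library, and another scaling gave -0.65 for the BMP targets.

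Day 6 cSKO cells, set against SEO for the amnion program, carried fewer amnion and surface ectoderm transcripts. Of 11 measured amnion markers 7 were at least 2-fold lower in cSKO and none 2-fold higher (median log2 ratio -1.19, counting interval -1.35 to -1.12, percentile 0). GABRP, a subunit of a GABA receptor, was at 162 CPM (156 to 169) against 522 CPM (513 to 531), the transcription factor genes GATA2 and GATA3 at 5.91 against 21.7 and 65.1 against 183 and the integrin gene ITGB6 at 26.3 against 81.4 CPM. All 5 measured periderm genes were at least 2-fold lower (median log2 ratio -1.39, counting interval -1.68 to -1.21, percentile 0), including KRT7 at 7.34 against 93.1 and CLDN4, a tight junction gene, at 44 against 105 CPM. Targets of FGF signalling went the other way, with 8 of 10 at least 2-fold higher in cSKO and 1 lower (median log2 ratio 1.94, counting interval 1.73 to 2.06, percentile 100). SPRY1 and DUSP6, feedback inhibitors of the pathway, stood at 81.8 against 12.3 and 46 against 9.89, and the effectors ETV4 and ETV5 at 17.2 against 1.81 and 19.7 against 3.28 CPM. BMP targets had a median of -0.70, with 3 of 10 at least 2-fold lower and none 2-fold higher. The list went both ways, since ID3 was at 350 against 255 and HEY1 at 46.1 against 23.8 CPM.

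Among single genes, RAMP1, a receptor-modifying protein gene, was at 232 CPM (225 to 239) against 18.6 CPM (16.9 to 20.4) in cSKO and SEO, MIR205HG at 247 against 23.3, the transcription factor gene MAF at 212 against 26.1 and LPL at 339 against 73.5 CPM. FST, which encodes the activin antagonist follistatin, was at 21.6 CPM (19.4 to 23.9) against 255 CPM (248 to 261), and CGA at 6.02 against 84.1 CPM. TP63, the master regulator of stratified epithelium, was near the floor at 5.45 against 0.780, and the neural crest list had a median of 0.36 with 2 of 8 genes at least 2-fold higher, INKA1 at 23.2 against 5.13 and TWIST1 at 10.6 against 3.24 CPM, and none lower. Of 9 stress genes, which respond to tissue dissociation, 5 were at least 2-fold lower in cSKO (median log2 ratio -1.18), among them ATF3 at 22.8 against 184 and FOS at 169 against 618 CPM.

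Day 6 LPM cells showed a mesodermal and posterior profile beside SEO. Of 10 measured lateral plate genes 7 were at least 2-fold higher and none 2-fold lower (median log2 ratio 3.31, counting interval 3.06 to 3.50, percentile 100). PITX1, a hindlimb and ventral body wall regulator, was at 265 CPM (255 to 276) against 3.69 CPM (2.97 to 4.54), HAND2 at 274 against 9.44, GATA6 at 72.2 against 2.95 and FOXF1 at 15.5 against 0.123 CPM. HAND1 was at 217 against 313 CPM. The endothelial list was at least 2-fold higher for 8 of 8 genes (median log2 ratio 3.83, counting interval 3.66 to 4.05, percentile 100), with KDR, a receptor of vascular endothelial growth factor, at 236 against 4.76 and CLDN5 at 56 against 2.75 CPM. Of the fibroblast list 9 of 10 were at least 2-fold higher and 1 lower (median log2 ratio 2.78, counting interval 2.74 to 2.83, percentile 100), such as PRRX1 at 346 against 6.65 and POSTN, a matrix protein gene, at 450.3 against 6.69 CPM. HOX genes, which mark position along the body axis, lay higher for 9 of 10 of paralog groups 5 to 9 and lower for 1 (median log2 ratio 3.85, counting interval 3.65 to 4.04, percentile 100) and 5 of 5 of groups 10 to 13 (median log2 ratio 4.37, counting interval 4.09 to 4.64, percentile 100), with HOXB9 at 70.1 against 0.739, HOXA10 at 72 against 0.615 and HOXA13 at 66.5 against 0.780 CPM.

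Amnion markers lay lower in LPM for 9 of 11 genes (median log2 ratio -2.28, counting interval -2.68 to -2.12, percentile 0), with GABRP at 22 against 522 and VTCN1, an immune checkpoint ligand gene, at 10.0 against 253 CPM. The exception at 2-fold or more was IGFBP3 at 2905 against 666 CPM, named after its value was seen. Cranial mesenchyme genes were lower in 5 of 5 cases (median log2 ratio -2.61, counting interval -2.80 to -2.37, percentile 0.06), TFAP2B at 9.24 against 159.8 CPM. Among the genes with the highest ratios were CXCL14 at 5439.8 CPM (5391 to 5489) against 72.5 CPM (69.1 to 75.9), the somatostatin gene SST at 1139 against 14.4, the WNT agonist gene RSPO3 at 752 against 13.7 and the proteoglycan gene VCAN at 1586 against 47.4 CPM. With a pseudocount of 10 CPM the lateral plate median was 1.05, because several members sat near 0 in SEO. A UMI of GABRP was found in 79.6% of SEO, 71.5% of SEO with LDN, 52.5% of cSKO and 13.5% of LPM cells. After thinning every cell to 2000 UMIs these shares were 53.9, 46.5, 22.2 and 2.67%, with 6, 10, 6 and 90 cells too shallow. In LPM a GABRP UMI was in 13.2% of mesenchyme-like cells and, in a count added after the values were seen, 11 of 101 endothelial-like cells (10.9%, 5.56 to 18.7%), at medians of 8855 and 6907 UMIs. The intervals of both classes overlap, so the LPM share is not read as expression.

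At day 28 SE held 48.1% (47 to 49.2%) amnion-like, 23.1% (22.2 to 24.1%) mesenchyme-like, 7.61% (7.04 to 8.21%) glia or neural crest-like and 5.91% (5.41 to 6.45%) chondrocyte-like cells. Amnioid held 58.8% (57.7 to 59.9%) mesenchyme-like and 5.85% (5.34 to 6.40%) amnion-like cells, with small endothelial-like, neural progenitor-like and skeletal muscle-like groups at 0.467%, 2.98% and 0.428%. In cSKO the shares were 72.8% (72 to 73.7%) mesenchyme-like, 13% (12.4 to 13.7%) epidermal-like and 4.50% (4.12 to 4.89%) amnion-like. Unnamed clusters held 14.5% of SE, 30.1% of Amnioid and 5.16% of cSKO cells. Those of Amnioid included clusters whose leading genes held PAX3 and LBX1, regulators of muscle precursors, and those of SE a cluster of 3.66% of cells led by the sarcomere genes MYLPF, ACTC1 and TTN. Median depth differed, from 6872 UMIs per cell in cSKO to 13807 in Amnioid.

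In day 28 Amnioid against SE amnion markers lay lower in the summed transcripts. Of 9 measured amnion markers 8 were at least 2-fold lower in Amnioid (median log2 ratio -3.26, counting interval -3.35 to -3.17, percentile 0). GABRP was at 69.5 CPM (68 to 71) against 899.7 CPM (894 to 906), TFAP2B at 8.63 against 136, ITGB6 at 8.55 against 124 and VTCN1 at 10.3 against 144 CPM. All 3 measured basal keratinocyte genes lay at least 2-fold lower (median log2 ratio -2.50, counting interval -2.65 to -2.36, percentile 0.09), among them DST at 65.9 against 182 and ITGA6 at 2.72 against 23 CPM, neither of which is restricted to keratinocytes. KRT5 and TP63 were at 0.00864 against 0.317 and 0.0346 against 0.287 CPM, both near 0. Glial genes were lower in 8 of 9 cases and higher in 1 (median log2 ratio -3.29, counting interval -3.42 to -3.23, percentile 0), with SOX10, a neural crest regulator, at 0.665 against 19.8 and S100B at 6.19 against 98.5 CPM.

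Higher in Amnioid were HOX groups 5 to 9 for 8 of 9 genes (median log2 ratio 3.85, counting interval 3.79 to 4.0, percentile 100) and groups 10 to 13 for 5 of 5 genes (median log2 ratio 3.63, counting interval 3.54 to 3.72, percentile 100), with HOXC8 at 31.3 against 0.198 and HOXA10 at 46.3 against 0.0891 CPM. Fibroblast genes were at least 2-fold higher in 6 of 11 cases and lower in 3 (median log2 ratio 1.29, counting interval 1.28 to 1.30, percentile 100), since the matrix gene DCN was at 2190.4 against 374 while PRRX1 was at 147 against 635 CPM. Lateral plate genes split as well, 3 of 7 at least 2-fold higher and 1 lower (median log2 ratio -0.11). DLK1, a regulator of progenitor cells, stood at 2893 CPM (2883 to 2903) against 57.6 CPM (56.2 to 59.1), the basement membrane collagen gene COL15A1 at 532 CPM (528 to 536) against 1.66 CPM (1.42 to 1.93), PITX1 at 186 against 0.317, and FLT1, a vascular growth factor receptor gene, at 144 against 1.38 CPM. HPGD, which degrades prostaglandins, was at 9.82 against 219.7, the retinol dehydrogenase gene RDH10 at 12.4 against 246 and the enkephalin gene PENK at 0.890 against 96.1 CPM. Of 9 stress genes 8 were at least 2-fold lower in Amnioid, FOS at 610.4 against 1406 CPM. The median of all genes measured in both lay at -0.33 in this pair, so medians between that value and 0 carry no direction. Counting every basal keratinocyte gene, including those below 5 CPM, gave a median of -0.88, and a pseudocount of 10 CPM gave -1.34.

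Day 28 cSKO against SE was read for neural crest and epidermal genes, although the labels leave open whether SE had received LDN. Of 8 measured neural crest genes 3 were at least 2-fold higher in cSKO and 1 lower (median log2 ratio 0.64, counting interval 0.56 to 0.70, percentile 99.9). TWIST1, also a mesenchymal regulator, was at 317 CPM (313 to 321) against 70.8 CPM (69.1 to 72.4), PAX3 at 11.8 against 2.22 and INKA1 at 32 against 14.9, while TFAP2A was at 30.7 against 72.5 and SOX10 at 10.4 against 19.8 CPM. A SOX10 UMI was found in 3.32% of cSKO and 8.45% of SE cells, or 1.51 and 3.16% after thinning, with 248 and 4 cells too shallow. Glia or neural crest-like cells numbered 333 of 11299 in cSKO. The list median is therefore not read as more neural crest cells in cSKO. Basal keratinocyte genes were higher in 5 of 8 cases (median log2 ratio 2.15, counting interval 2.07 to 2.23, percentile 100). The basal keratin genes KRT5 and KRT15 were at 78.6 CPM (76.7 to 80.5) against 0.317 CPM (0.217 to 0.447) and 83.5 CPM (81.5 to 85.5) against 1.14 CPM (0.940 to 1.37), the hemidesmosome gene COL17A1 at 31.6 against 0.980 and TP63 at 11.5 against 0.287 CPM. Amnion genes were lower in 7 of 10 cases (median log2 ratio -2.09, counting interval -2.18 to -2.0, percentile 0), with ITGB6 at 9.68 against 124 and GABRP at 147 against 899.7 CPM, and the exception at 2-fold or more was MUC16 at 8.26 against 1.78 CPM, named after its value was seen. Fibroblast genes had a median of 0.59 with 4 of 12 at least 2-fold higher and 1 lower, such as TWIST2 at 121 against 11.6 and PDGFRA at 224 against 64.9 CPM. Targets of WNT signalling had a median of 0.60, with LEF1 at 81.7 against 12.1 and NKD1 at 50.9 against 10.0 CPM.

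CXCL14 was at 4795 CPM (4781 to 4810.2) against 164 CPM (162 to 167) in cSKO and SE, the WNT inhibitor gene APCDD1 at 229 against 10.6, MGP, an inhibitor of mineralisation, at 650.3 against 110.3 and TTR, the transthyretin gene expressed by choroid plexus, at 244 against 17.4 CPM. Lower in cSKO were SLN at 22 against 443, KRT18, a simple epithelial keratin gene, at 115 against 1063, the growth factor gene AREG at 3.02 against 108 and HAND1 at 24.2 against 244 CPM. SLN was a leading gene of amnion-like clusters in both samples. A KRT5 UMI was found in 16.1% of cSKO cells, or 8.47% after thinning with 248 cells too shallow. Mesenchyme-like cells of the same library, which should lack KRT5, gave 5.95% at a median of 6366.5 UMIs against 6872 in all cells. Both a pseudocount of 10 CPM and the count of every member moved the neural crest median, to 0.36 and 0.16.

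Amnioid and cSKO of day 28 were also set directly against each other. The amnion list had a median of -0.75, with 4 of 10 genes at least 2-fold lower in Amnioid and 1 higher. All 8 measured basal keratinocyte genes were at least 2-fold lower in Amnioid (median log2 ratio -3.65, counting interval -3.73 to -3.57, percentile 0), KRT15 at 0.121 against 83.5 CPM. Cranial mesenchyme genes were lower in 3 of 4 cases, ALX4 at 1.55 against 29.5, and WNT targets in 6 of 7, LEF1 at 7.99 against 81.7 CPM. HOX groups 5 to 9 were higher for 7 of 9 genes (median log2 ratio 4.0, counting interval 3.86 to 4.13, percentile 100), HOXB7 at 34.2 against 0.226 CPM. All 4 measured cardiomyocyte genes were higher in Amnioid (median log2 ratio 4.92, counting interval 4.82 to 5.02, percentile 100), as TNNI1, a slow muscle troponin gene, at 236 CPM (233 to 239) against 1.93 CPM (1.64 to 2.25), TNNT2 at 298 against 28.2 and MYL4 at 60.2 against 0.143 CPM. The other list members, MYH6, NKX2-5, ACTN2 and NPPA, stayed below 5 CPM in both, and no cluster of either sample was cardiomyocyte-like. The list is therefore not read as heart muscle. DLK1 was at 2893 CPM (2883 to 2903) against 41.9 CPM (40.5 to 43.3) and TTR at 0.0605 against 244 CPM. The median of all genes lay at -0.29.

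**Figure D2:**
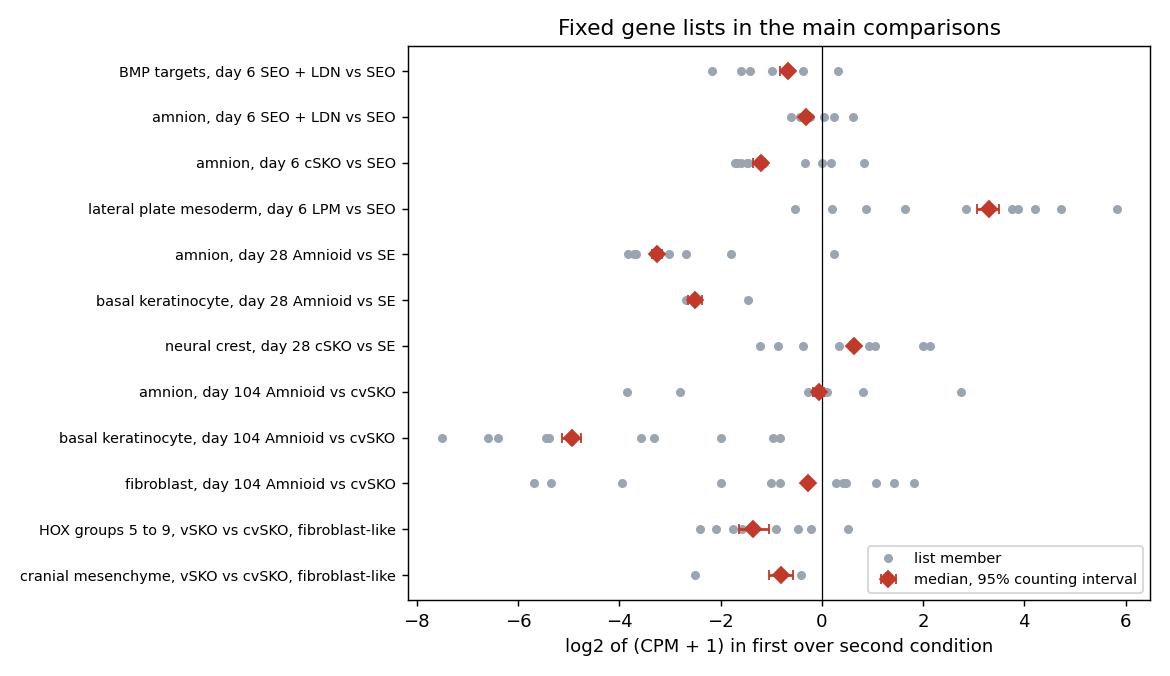
Ratios of the members of the gene lists chosen beforehand for each main comparison (grey points; horizontal axis, log2 of CPM + 1 in the first over the second condition) and their medians with 95% counting intervals (red diamonds) (vertical axis). Other lists are not shown. Medians of the lists shown ran from -4.93 for basal keratinocyte genes in day 104 Amnioid against cvSKO to 3.31 for lateral plate mesoderm genes in day 6 LPM against SEO.

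At day 104 Amnioid held 66.3% (64.8 to 67.7%) mesenchyme-like and 3.31% (2.78 to 3.90%) amnion-like cells, and 30.4% of cells were unnamed for low depth. The cvSKO sample held 41.2% (40.4 to 42%) mesenchyme-like, 38.8% (38 to 39.5%) epidermal-like, 3.40% (3.11 to 3.71%) amnion-like, 2.65% (2.40 to 2.93%) melanocyte-like, 0.550% (0.437 to 0.683%) skeletal muscle-like and 0.292% (0.211 to 0.393%) Merkel-like cells. An unnamed fibroblast-closest cluster, with 12 of 12 fibroblast markers, held 12.2% of its cells. Median depth was 14513.5 UMIs in Amnioid and 3468.5 in cvSKO.

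Day 104 Amnioid against cvSKO asked which amnion and which skin genes set them apart. Skin epithelium was nearly absent from Amnioid in the summed counts. Of 11 measured basal keratinocyte genes 9 were at least 2-fold lower in Amnioid (median log2 ratio -4.93, counting interval -5.13 to -4.75, percentile 0), as were all 12 suprabasal genes (median log2 ratio -6.44, counting interval -6.56 to -6.32, percentile 0) and all 10 hair follicle genes (median log2 ratio -4.85, counting interval -4.90 to -4.80, percentile 0). KRT5 was at 1.47 CPM (1.16 to 1.84) against 447 CPM (442 to 453), TP63 at 0.0765 against 46.1, KRT1, a keratin gene of differentiating epidermis, at 0.0382 against 561, KRTDAP at 0.306 against 2773 and TCHH, the trichohyalin gene of the inner root sheath, at 0.0382 against 386 CPM. Melanocyte genes were lower in 6 of 6 cases (median log2 ratio -4.87, counting interval -5.01 to -4.74, percentile 0), DCT and TYRP1, both of melanin synthesis, at 1.07 against 96.5 and 0.191 against 81.4 CPM. The amnion list had a median near 0 (median log2 ratio -0.05, counting interval -0.17 to 0.05, percentile 79.1), with IGFBP3 at 2783 against 414 and GABRP at 69.2 against 38.7 but GATA3 at 5.78 against 96.8 and TFAP2B at 5.07 against 41.4 CPM, and skin epithelium also expresses GATA3 and TFAP2B.

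The fibroblast list split, with 3 of 12 at least 2-fold higher in Amnioid and 5 lower (median log2 ratio -0.27, counting interval -0.29 to -0.24, percentile 10.6). TWIST2 was at 8.85 against 151, DPT at 0.612 against 81.7 and PRRX1 at 111 against 444 CPM. HOX groups 5 to 9 were higher in Amnioid for 9 of 11 genes and lower for 1 (median log2 ratio 2.07, counting interval 1.91 to 2.24, percentile 100), HOXB9 at 33.1 against 3.0 and HOXC6 at 34.4 against 4.69 CPM. Lateral plate genes were higher in 5 of 9 cases (median log2 ratio 1.43, counting interval 1.22 to 1.67, percentile 100), HAND2 at 251 against 41.8 and GATA6 at 46.5 against 4.69 CPM. Cell cycle genes were lower in 9 of 10 cases (median log2 ratio -1.94, counting interval -2.0 to -1.85, percentile 0), MKI67 at 9.03 against 52.3 CPM. DLK1 was at 11979.9 CPM (11950.2 to 12009.6) against 921 CPM (913 to 929), MGP at 3711 against 287, VTN, which encodes vitronectin, at 274 against 6.89 and WNT2 at 154 against 2.11 CPM. The median of all genes lay at -0.22. Median-of-ratios size factors brought the amnion median to 0.16 and moved the fibroblast median to -0.03, so neither list carries a direction, and a pseudocount of 10 CPM moved the basal keratinocyte median to -2.48.

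Within mesenchyme-like cells of day 104, of which 2706 were Amnioid and 6071 cvSKO, dermal condensate and papilla genes mostly lay lower in Amnioid. Of 9 dermal condensate and papilla genes 7 were at least 2-fold lower in Amnioid and 1 higher (median log2 ratio -2.79, counting interval -2.95 to -2.65, percentile 0), with PTCH1, the hedgehog receptor and a target of the pathway, at 1.75 CPM (1.39 to 2.16) against 302 CPM (294 to 310.2) and TRPS1 at 39.3 against 463 CPM. All 9 measured WNT targets were lower as well (median log2 ratio -2.37, counting interval -2.49 to -2.13, percentile 0.01), LEF1 at 9.05 against 68.6 CPM. HOX groups 5 to 9 kept a higher median in Amnioid, with 7 of 11 at least 2-fold higher and 2 lower (median log2 ratio 1.21, counting interval 1.04 to 1.33, percentile 100). KRT5 at 0.291 against 75.8 and KRTDAP at 0.208 against 205 CPM show how much keratinocyte RNA the cvSKO cells of this class carried. The class is made of separate clusters in each library, and the median of all genes lay at -0.32. The dermal condensate and papilla list also names clusters of this class. A cvSKO cluster of 595 cells entered closest to that list and no Amnioid cluster did, so the list is not independent of the class. The unnamed fibroblast-closest cvSKO cluster of 1798 cells was left out, and no alternative added it here.

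At day 128 vSKO held 45.2% (43.6 to 46.9%) epidermal-like, 44% (42.3 to 45.6%) mesenchyme-like and 4.25% (3.61 to 4.97%) melanocyte-like cells, with 6.58% unnamed. No cluster was amnion-like, which sets no bound on single cells, and a GABRP UMI was found in 5 of 3526 cells. A KRT5 UMI was found in 41.4% of vSKO and 36.5% of cvSKO cells at medians of 11277 and 3468.5 UMIs. Thinned to 2000 UMIs both stood at 32.5%, with 73 vSKO and 3526 cvSKO cells too shallow. In cvSKO median depth was 2505 UMIs in mesenchyme-like and 4238 in epidermal-like cells. The cells deep enough to thin need not hold these classes in the same proportion as all cells. The equal thinned shares are therefore not read as equal shares of all cells. Mesenchyme-like cells gave 3.29% in vSKO and 13.6% in cvSKO, at 10209 and 2505 UMIs.

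The skin organoids were compared for genes of body position within fibroblast-like cells, from the mesenchyme-like clusters closest to the fibroblast list, 1144 of vSKO and 5252 of cvSKO. HOX groups 5 to 9 lay lower in vSKO for 5 of 9 genes and at least 2-fold higher for none (median log2 ratio -1.36, counting interval -1.63 to -1.04, percentile 0.25), with HOXB9 at 0.685 CPM (0.329 to 1.26) against 7.87 CPM (6.58 to 9.35), HOXC8 at 3.84 against 13.3 and HOXC6 at 2.74 against 11.7 CPM. The lateral plate genes HAND2 and PITX1 were at 5.69 against 105 and 0.891 against 18.1 CPM. Both were named for their large ratios and do not stand for the list. Over all cells its members BNC2 and TBX3, named after their values were seen, were at 63.3 against 84.5 and 21.6 against 19.4 CPM. The cranial mesenchyme list rested on 3 genes, 1 of them at least 2-fold lower (median log2 ratio -0.81, counting interval -1.05 to -0.57, percentile 7.76), with ALX4 at 11.5 against 20.9 and TFAP2B at 0.343 against 6.66 CPM. Neither direction was stable. With doublet calls kept, the HOX median turned to 0.38 and the cranial median was -1.40. Over all cells the HOX median was -0.29 and the cranial median turned to 0.43. A pseudocount of 10 CPM gave -0.53 and -0.52. Adding unnamed fibroblast-closest clusters or counting every list member gave -0.89 and -0.90 for HOX and -0.55 and -0.45 for cranial genes, and equal weights for cells gave -0.53 for the latter.

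In the same cells the collagenase gene MMP1 was at 1218 CPM (1200.2 to 1236) against 4.78 CPM (3.79 to 5.96), the angiotensinogen gene AGT at 292 against 2.24, and SOD2, a mitochondrial superoxide dismutase gene, at 1233 against 73.6 CPM. DLK1 was at 123 CPM (118 to 129) against 2443 CPM (2419 to 2467) and COL15A1 at 44.6 against 565 CPM. All 10 cell cycle genes were at least 2-fold lower in vSKO (median log2 ratio -4.48, counting interval -4.71 to -4.33, percentile 0), TOP2A at 5.21 against 263 CPM. The median of all genes lay at 0.25. MTRNR2L12, at 337 against 0.363 CPM, resembles the mitochondrial ribosomal RNA gene in sequence, so its reads are uncertain.

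Over all cells vSKO carried less hair follicle RNA than cvSKO, with 9 of 10 genes at least 2-fold lower (median log2 ratio -4.15, counting interval -4.28 to -4.02, percentile 0). TCHH had 0 counts in vSKO and stood at 386 CPM in cvSKO, and KRT71 was at 0.0250 against 90.3 CPM. Basal keratinocyte genes were higher in 9 of 12 cases (median log2 ratio 1.52, counting interval 1.46 to 1.59, percentile 100.0), KRT14 at 573 CPM (566 to 581) against 88.2 CPM (85.8 to 90.8) and DST, a very long gene, at 1092 against 233 CPM. Suprabasal genes went both ways, LOR at 89.6 against 10.5 and KRTDAP at 762 against 2773 CPM. All 10 cell cycle genes were lower (median log2 ratio -3.45, counting interval -3.59 to -3.32, percentile 0), MKI67 at 0.451 against 52.3 CPM, and amnion genes were lower in 5 of 8 cases and higher in 1, GABRP at 0.275 against 38.7 and VTCN1 at 0.125 against 6.69 CPM. The median of all genes lay at 0.29, and long genes lay higher in vSKO: the longest 10% of genes exceeded the shortest 10% by 1.37 in median log2 ratio. Within epidermal-like cells hair follicle genes were again lower in 9 of 10 cases (median log2 ratio -4.93, counting interval -5.09 to -4.81, percentile 0), KRT25 having 0 counts in vSKO and 386 CPM in cvSKO. There the fibroblast list, foreign to this class, had a median of -5.50, with COL1A1 at 35.1 CPM (32.6 to 37.7) against 3561 CPM (3537 to 3585). Age, library and condition differ together between vSKO and cvSKO, so none can be told apart.

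**Figure D3:**
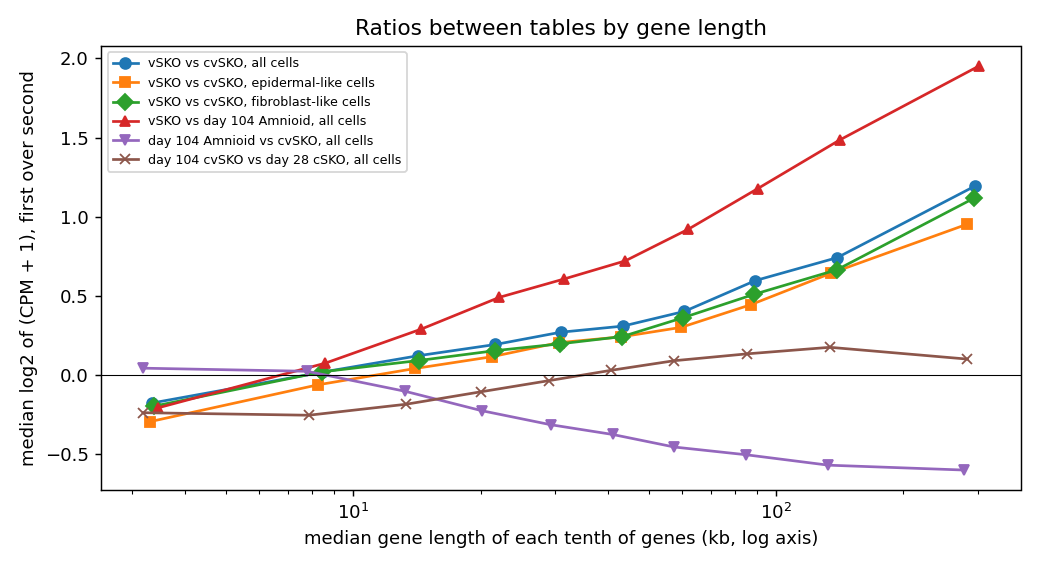
Median log2 ratio of CPM + 1 between tables (vertical axis) for groups of 10% of genes by length (horizontal axis, kb, log scale), one line per comparison. The longest 10% exceeded the shortest 10% by 1.37 in day 128 vSKO against day 104 cvSKO, while day 104 Amnioid against cvSKO gave -0.64.

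Set against day 104 Amnioid, vSKO was higher for all 12 basal keratinocyte genes (median log2 ratio 5.80, counting interval 5.66 to 5.94, percentile 100) and all 7 melanocyte genes (median log2 ratio 4.55, counting interval 4.30 to 4.66, percentile 100), KRT14 at 573 against 0.0574 and TYRP1 at 162 against 0.191 CPM. It was lower for 9 of 10 genes of HOX groups 5 to 9 (median log2 ratio -2.74, counting interval -2.88 to -2.59, percentile 0) and 6 of 9 lateral plate genes (median log2 ratio -3.52, counting interval -3.68 to -3.34, percentile 0), HOXB9 at 0.30 against 33.1 and HAND2 at 2.40 against 251 CPM. DLK1 was at 62.9 against 11979.9 and MGP at 24.9 against 3711 CPM. The median of all genes lay at 0.48, and the longest 10% of genes exceeded the shortest 10% by 2.16 in median log2 ratio, so values of long genes in this pair carry that trend.

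Over time, Amnioid at day 104 beside day 28 was lower for all 10 cell cycle genes (median log2 ratio -2.17, counting interval -2.23 to -2.09, percentile 0), all 4 measured cardiomyocyte genes (median log2 ratio -3.63, counting interval -3.71 to -3.56, percentile 0) and 4 of 5 neuron genes (median log2 ratio -3.39, counting interval -3.57 to -3.20, percentile 0), with TOP2A at 21.4 against 126, TNNI1 at 6.52 against 236 and NEFL at 0.153 against 13.1 CPM. No Amnioid cluster of either day was cardiomyocyte-like. Fibroblast genes were higher in 6 of 10 cases and lower in 1 (median log2 ratio 1.23, counting interval 1.22 to 1.23, percentile 100), COL1A1 at 12753 against 4534 and DCN at 7243 against 2190.4 CPM. NNMT, which methylates nicotinamide, was at 490.3 CPM (484 to 496) against 3.08 CPM (2.77 to 3.41), the prostaglandin D synthase gene PTGDS at 4319 against 217 and the growth factor gene FGF7 at 163 against 2.97 CPM. The amnion list had a median of -0.12 and HOX groups 5 to 9 one of 0.05.

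In the skin organoids, cvSKO at day 104 beside cSKO at day 28 was higher for all 12 suprabasal genes (median log2 ratio 5.38, counting interval 5.30 to 5.48, percentile 100), 9 of 10 hair follicle genes (median log2 ratio 4.84, counting interval 4.78 to 4.89, percentile 100) and all 6 melanocyte genes (median log2 ratio 3.89, counting interval 3.80 to 4.0, percentile 100). KRTDAP was at 2773 against 2.27, KRT5 at 447 against 78.6, KRT71 at 90.3 CPM against 0 counts, and DCT at 96.5 against 0.393 CPM. Skeletal muscle genes were higher in 5 of 5 cases, ACTA1 at 35.4 against 0.345 CPM. Neuron genes were lower in 6 of 7 cases (median log2 ratio -2.22, counting interval -2.38 to -2.10, percentile 0) and chondrocyte genes in 5 of 8 but higher in 3 (median log2 ratio -2.91, counting interval -3.02 to -2.79, percentile 0), the growth cone gene GAP43 at 4.89 against 288 and the cartilage collagen gene COL2A1 at 0.454 against 127 CPM. TTR was at 1.54 against 244 CPM. The labels of these samples differ, cSKO and cvSKO, so time and condition change together.

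Across the series the summed HOX transcripts of groups 5 to 9 reached 249.9 CPM (239.5 to 261) in day 6 LPM, 194 CPM (191 to 197) in day 28 Amnioid and 208 CPM (205 to 212) in day 104 Amnioid. They stood at 22.4 CPM (20.6 to 24.4) in day 6 SEO, 10.5 CPM (9.92 to 11.2) in day 28 SE, 11.3 CPM (10.6 to 12) in day 28 cSKO, 59 CPM (57 to 61) in day 104 cvSKO and 43.7 CPM (41.7 to 45.8) in day 128 vSKO. Groups 10 to 13 summed to 193 CPM in day 6 LPM and 23.6 CPM in day 104 cvSKO. These sums depend on how many cells of each class a sample held.

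**Figure D4:**
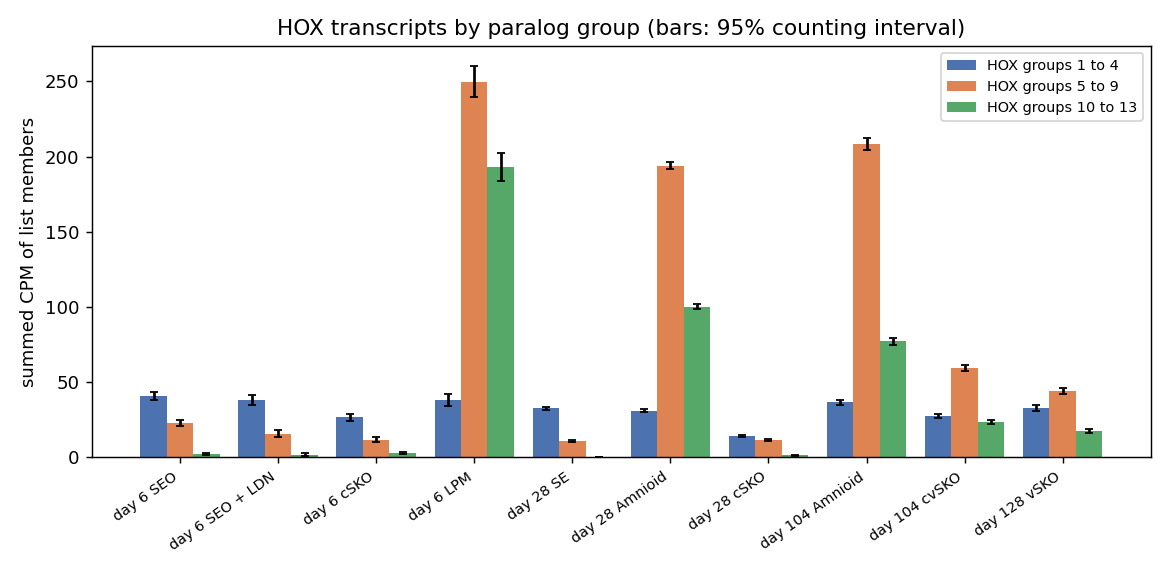
Summed CPM (vertical axis) of the HOX genes of paralog groups 1 to 4, 5 to 9 and 10 to 13 in each condition (horizontal axis), with 95% Poisson counting intervals and 1 sample per condition. Groups 5 to 9 reached 249.9 CPM in day 6 LPM against 22.4 CPM in day 6 SEO, and 208 CPM in day 104 Amnioid against 59 CPM in day 104 cvSKO.

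Genes followed in every condition have these places in the GRCh38 assembly by the GENCODE annotation: ISL1 on chromosome 5 from 51383391 to 51394738, GABRP on chromosome 5 from 170763350 to 170814047, VTCN1 on chromosome 1 from 117143587 to 117210960, TP63 on chromosome 3 from 189631416 to 189897279, KRT5 on chromosome 12 from 52514575 to 52520687, HAND1 on chromosome 5 from 154474972 to 154478264, SOX10 on chromosome 22 from 37970686 to 37987422, ID1 on chromosome 20 from 31605283 to 31606515 and ID3 on chromosome 1 from 23557918 to 23559794. ISL1, a regulator of amnion and heart progenitors, ran from 0.125 CPM in vSKO to 30.5 in day 28 SE and stood at 29.9 in day 6 SEO. GABRP ran from 0.275 CPM in vSKO to 899.7 in day 28 SE, and VTCN1 from 0.125 in vSKO to 253 in day 6 SEO. KRT5 had 0 UMIs in the 4 conditions of day 6 and reached 533 CPM in vSKO, where TP63 reached 98.9 CPM. HAND1 ran from 0.576 CPM in vSKO to 313 in day 6 SEO. SOX10 was at 19.8 CPM in day 28 SE and had 0 UMIs in day 104 Amnioid.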

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

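The list medians that answer the main comparisons, the class shares resting on 20 or more cells and the shares of cells with a UMI were recomputed with one choice changed at a time. Medians of the other lists have no alternative. The adjustment for gene length, the addition of unnamed clusters and the removal of cells of low depth were chosen after seeing the data. No paired analysis was possible because each condition is 1 sample and the results come from no test. Of 83 alternative list medians 42 stayed within the counting interval of the main value, 39 moved outside it and 2 changed the sign of a median whose interval excludes 0. Sign changes of the day 104 amnion median, whose interval includes 0, are not among the latter. Of 159 class shares 99 stayed within the interval and 60 moved, and thinning moved 61 of 70 shares of cells with a UMI. Summed UMIs limit values near 5 CPM, above all in day 6 LPM and in the class-limited sums. Beyond the pseudocount, the cause was not tested.

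With a pseudocount of 10 CPM in place of 1, which shrinks the ratios of genes with few counts by construction, the median was -0.64 for BMP targets, day 6 SEO + LDN against SEO, -0.53 for HOX groups 5 to 9, vSKO against cvSKO, -2.43 for amnion list, day 28 Amnioid against SE, -1.0 for amnion list, day 6 cSKO against SEO and -2.48 for basal keratinocyte list, day 104 Amnioid against cvSKO. The same setting gave -1.34 for basal keratinocyte list, day 28 Amnioid against SE, -0.52 for cranial mesenchyme list, vSKO against cvSKO, 1.05 for lateral plate mesoderm list, day 6 LPM against SEO and 0.36 for neural crest list, day 28 cSKO against SE. Under median-of-ratios size factors it was -0.65 for BMP targets, day 6 SEO + LDN against SEO, 0.16 for amnion list, day 104 Amnioid against cvSKO, -2.93 for amnion list, day 28 Amnioid against SE, -2.25 for basal keratinocyte list, day 28 Amnioid against SE and -1.06 for cranial mesenchyme list, vSKO against cvSKO. The same setting gave -0.034 for fibroblast list, day 104 Amnioid against cvSKO. With cells weighted equally it was -0.91 for HOX groups 5 to 9, vSKO against cvSKO, 0.16 for amnion list, day 104 Amnioid against cvSKO, -2.99 for amnion list, day 28 Amnioid against SE, -3.96 for basal keratinocyte list, day 104 Amnioid against cvSKO and -2.27 for basal keratinocyte list, day 28 Amnioid against SE. The same setting gave -0.53 for cranial mesenchyme list, vSKO against cvSKO and -0.35 for fibroblast list, day 104 Amnioid against cvSKO. With doublet calls kept it was 0.38 for HOX groups 5 to 9, vSKO against cvSKO, -1.40 for cranial mesenchyme list, vSKO against cvSKO and -0.29 for fibroblast list, day 104 Amnioid against cvSKO. With every list member counted, including those below 5 CPM, it was -0.90 for HOX groups 5 to 9, vSKO against cvSKO, -0.17 for amnion list, day 104 Amnioid against cvSKO, -2.85 for amnion list, day 28 Amnioid against SE, -4.25 for basal keratinocyte list, day 104 Amnioid against cvSKO and -0.88 for basal keratinocyte list, day 28 Amnioid against SE. The same setting gave -0.45 for cranial mesenchyme list, vSKO against cvSKO, 2.25 for lateral plate mesoderm list, day 6 LPM against SEO and 0.16 for neural crest list, day 28 cSKO against SE. At Leiden resolution 2 it was -1.03 for HOX groups 5 to 9, vSKO against cvSKO. Over all cells in place of fibroblast-like cells it was -0.29 for HOX groups 5 to 9, vSKO against cvSKO and 0.43 for cranial mesenchyme list, vSKO against cvSKO. With the unnamed fibroblast-closest clusters added it was -0.89 for HOX groups 5 to 9, vSKO against cvSKO and -0.55 for cranial mesenchyme list, vSKO against cvSKO. With cells of low depth left out it was -5.16 for basal keratinocyte list, day 104 Amnioid against cvSKO. With at least 1000 genes and under 10% mitochondrial UMIs per cell it was -1.04 for HOX groups 5 to 9, vSKO against cvSKO. With the median of genes of like length subtracted it was -1.05 for cranial mesenchyme list, vSKO against cvSKO.

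At Leiden resolution 2, the amnion-like share was 2.88% in day 104 cvSKO, 45.4% in day 28 SE, 40.3% in day 6 SEO, 35.8% in day 6 SEO + LDN and 9.35% in day 6 cSKO. Under that setting the mesenchyme-like share was 46.9% in day 104 cvSKO, 63.4% in day 28 Amnioid, 29.5% in day 28 SE and 65.8% in day 28 cSKO. With doublet calls kept, the amnion-like share was 44.5% in day 28 SE, 55.4% in day 6 SEO, 47.3% in day 6 SEO + LDN and 9.76% in day 6 cSKO. Under that setting the epidermal-like share was 41.2% in day 104 cvSKO and 14.6% in day 28 cSKO. Under that setting the mesenchyme-like share was 31.9% in day 104 cvSKO, 69.2% in day 28 Amnioid, 24.8% in day 28 SE and 65.4% in day 28 cSKO. With cells of 1000 or more genes and under 10% mitochondrial UMIs, the amnion-like share was 64% in day 6 SEO, 54.6% in day 6 SEO + LDN and 11.3% in day 6 cSKO. That filter left 1991 of 1992 SEO, 978 of 982 SEO + LDN and 1432 of 1433 cSKO cells of day 6. Their shares therefore moved through new clustering and naming of the day 6 pool, not through loss of their own cells. Under that setting the epidermal-like share was 41.9% in day 104 cvSKO. Under that setting the mesenchyme-like share was 84.5% in day 104 Amnioid, 39.4% in day 104 cvSKO, 60.0% in day 28 Amnioid and 63.2% in day 28 cSKO.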

Other observations

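Among the tests below, the search for genes found in the vSKO table alone was chosen after the result had been seen, and the genes and lists of the next paragraphs were read off after the values were known.

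In amnion-like cells of day 28 cSKO against SE, several genes with high ratios were ones that interferon induces. In 508 against 3880 cells the ubiquitin-like gene ISG15 was at 326 CPM (310.3 to 342) against 26.5 CPM (25.1 to 27.9), the antiviral GTPase gene MX1 at 77.3 against 5.92, IFI44L at 55.4 against 1.97 and BST2, which tethers virions, at 63.4 against 4.75 CPM. The amnion list differed less there (median log2 ratio -0.35, 2 of 10 members at least 2-fold lower and 1 higher). That list also named these clusters, so small amnion medians within the class do not show that its cells were alike between samples. IFI44L was also a leading gene of a mesenchyme-like cluster of cSKO, so the difference is not shown to belong to amnion-like cells. In the 451 amnion-like cells of day 28 Amnioid ISG15 was at 241 against 26.5 CPM of SE, and the amnion list had a median of -0.06, closer to 0 than the median of all genes at -0.17. Hypoxia and glycolysis genes had a median of 0.98 in that pair, 4 of 9 of them at least 2-fold higher. At day 104 the 501 amnion-like cells of cvSKO and 135 of Amnioid had an amnion list median of -0.18, with suprabasal keratinocyte genes at 3.28 and fibroblast genes at 3.03. Melanocyte genes were at 3.73 and hair follicle genes at 3.45 there, as RNA from other cells of the cvSKO library would give, so none of these is read as expression of the class. No interferon list had been fixed, and each class is a separate cluster of a separate library.

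FGF and WNT targets at day 104 lay lower in Amnioid than in cvSKO, where the median of all genes was -0.22. FGF targets had a median of -1.83 with 6 of 8 at least 2-fold lower, and WNT targets one of -1.98 with 6 of 9. BMP targets went both ways (median log2 ratio -0.64, 5 of 11 lower and 1 higher), with ID1 at 5.76 against 210.3 and BAMBI at 91.6 against 17.6 CPM. In day 28 Amnioid against SE skeletal muscle genes had a median of 1.75 with 3 of 4 at least 2-fold higher, yet 3.66% of SE cells lay in an unnamed cluster led by sarcomere genes and 0.428% of Amnioid cells were skeletal muscle-like. Endothelial genes had a median of 1.51, 2 of 4 of them higher and 1 lower. By day 104 the skeletal muscle median of Amnioid against its day 28 value was -3.93, while hypoxia and glycolysis genes were at 1.33. The same list was at 3.21 in day 104 cvSKO against day 28 cSKO, all 10 measured members being at least 2-fold higher. Fibroblast-like cells of vSKO carried the chemokine genes CXCL1 at 253 against 6.48 and CXCL2 at 296 against 7.27 CPM of cvSKO, and 8 of 10 stress genes were at least 2-fold higher (median log2 ratio 2.19, counting interval 2.12 to 2.27, percentile 100.0), with HSPA1A at 30.6 against 3.27 CPM, a gene with a near-identical copy whose reads are uncertain. Tissue dissociation induces such genes too, and how each library was dissociated was not compared.

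Genes lay higher in vSKO than in cvSKO the longer they were. The smallest difference between the longest and the shortest 10% of genes, over all cells, epidermal-like and fibroblast-like cells, was 1.25 in log2, against -0.64 for Amnioid over cvSKO. Reads in introns counted in one table and left out of the other may account for the trend, which both classes tested shared. Other gene models or another reference behind the vSKO table cannot be told: 0 genes at 50 CPM or more were found in that table alone, but such a cause needs none, and MTRNR2L12, at 340.0 against 0.436 CPM, goes with a difference in counting or reference. Age, library and condition change with the table and stay open as untested explanations, and subtracting the median of genes of like length, an adjustment added after the data had been seen, left the HOX median of fibroblast-like cells at -1.37.

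Epidermal-like cells of cvSKO carried 63.7 UMIs per cell of 50 fibroblast transcripts, melanocyte-like cells 63.9, amnion-like cells 94.2 and mesenchyme-like cells 191. Doublets that escaped the calls are argued against as the only source, since a COL1A1 UMI was in 97.7% of epidermal-like cells, 0.978 of the share that an even spread gives. An even spread would give 99.9%, so nearly every cell holds a UMI. The share therefore cannot tell which source gave most of the UMIs. Free RNA from lysed cells may be the source, as the largest class mean was 1.48 times the smallest among the 3 classes. No biological explanation was tested, and the fibroblast values of these classes carry no statement about their own expression.

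Amnion-like cells in cvSKO numbered 501. Reads carried over from the day 104 Amnioid library under the same barcode are argued against, since 2 of these cells, or 0.399%, shared a barcode with that table, beside 0.0914% of other cells. Whole cells carried between samples before capture were not tested. Day 28 cSKO held 508 amnion-like cells, and no biological explanation was tested.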
